A study of Homo sapiens with 2 samples.

How the data were processed

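Total RNA from MDA-MB-231 cells was measured on 2 Affymetrix expression arrays, 1 of parental control cells and 1 of a clone with stable UGT8 knockdown. Per the labels, RNA was extracted with Trizol, and biotin-labelled cRNA was made from it by the Affymetrix protocol. Both groups had the same growth and harvest protocol per the labels. The knockdown reagent and any vector control are not given in the sources used here. Scanner files were not analysed here.

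The deposited values are RMA values on the log2 scale, per the submitters' processing notes. RMA corrects the background of each array, normalizes between arrays and summarises the probes of a probe set. The software, its version and the genome build are not given in the sources used here. The sorted values of both arrays nearly coincide, with a largest gap of 0.0727, as normalization between arrays leaves them. Such normalization removes a shift common to most transcripts, so each difference is relative to the bulk of the transcripts. The control array ranged from 2.72 to 14.3 and the knockdown array from 2.67 to 14.4.

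Probe sets were named through the platform's annotation table, whose symbols were updated to those of NCBI RefSeq's table for GRCh38.p14, in which 18201 of the 18244 symbols (99.8%) were found. No coordinates are given because the build behind the array values is not named. Of 49495 probe sets, 102 were controls, 45278 had 1 gene symbol, 1333 had several and 2782 had none in the table used. Only those with 1 symbol were used for genes. A gene was read by its probe set with the highest mean over both arrays. A floor was set at the median mean level of all non-control probe sets (log2 6.64), which left 10439 genes. Over 6067 genes with at least 2 probe sets past the floor, the median SD of the difference between probe sets of 1 gene was 0.0832. This SD covers disagreement of probe sets within 1 pair of arrays and is no replicate error. Some probe sets of 1 gene gave the same difference, as the 2 of CXCL2 did, so they are not all independent readings and can lower this SD.

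The groups were taken from the genotype labels. The main setting, the gene lists, the rule for named genes and all alternatives but those on spike-in controls were fixed before the data were examined. The difference was the knockdown value minus the control value. No test was run and no p-value is given, because each group holds 1 array. Genes were counted at a 2-fold difference. The genes named were UGT8 in all its probe sets and the 12 with the largest differences in each direction. Genes with another probe set past the floor of opposite sign, without a proper symbol or linked to the Y chromosome, and XIST, were passed over. For each gene list the rule took up to 4 measured members with the largest absolute difference of at least 1.5-fold. ITGAV, ITGB5, GAL3ST1, GALC, ARSA and UGCG were named in advance. The mesenchymal markers VIM, CDH2, SPARC, ACTA2 and TAGLN were named after their values were seen, to complete a small count. ITGAE, ITGB1, CCN1, CTSD, ISG15, CASP2, BIK, PDGFA, IGF1R, SPRY2 and XPC were also named after their values were seen, to complete small counts. So were MMP3, TIMP4, ST6GALNAC5, CCL20, AKR1C1, PDGFRB and FGFR3, list members below the floor that read above it on 1 array and differed by at least 1.5-fold.

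The 42 gene lists covered sphingolipid metabolism, adhesion, signalling, cell cycle, metabolism, stress, cell identity and markers of other cell types. They held 976 genes, of which 69 had no probe set with 1 symbol. For each list with at least 5 genes past the floor, the median difference was set against 10000 random lists of the same size. These were drawn from the genes past the floor within 20 bins of mean level. A list was called outside at a percentile of 2.5 or below or of 97.5 or above. Random genes are not coexpressed as list members are, so the percentile is a description of these arrays and not a test of the conditions.

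The procedure was tested on simulated differences with the real genes, in 200 draws with lists of 25 genes. Lists with no shift were outside in 2.5% of draws, and lists shifted by 0.25 in 92.5%. Of 200 genes changed by 2-fold, 52.5% were counted at the 2-fold threshold, and of those changed by 3-fold, 99.5%. The spread given to these genes was drawn from the real differences with the largest in absolute size left out. Both shares thus follow largely from the distance of the change to the threshold and are no estimate of sensitivity.

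Alternatives changed 1 choice at a time. They were a fold threshold of 1.5 or 3, no floor, a floor at the 25th or 75th percentile, the mean over all probe sets of a gene, each probe set singly, leaving out probe sets whose names mark cross-hybridisation (_s_at and _x_at), and centring on the median or by a loess curve with a fraction of 0.3. Centring on the hybridisation or poly-A spike-in controls was added after the data were seen. Of the gene families examined after that, 1 is not reported here. Python 3.11.15 was used with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9.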

Results

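Gene expression was measured in MDA-MB-231 cells, a human breast carcinoma line of basal and mesenchymal character that lacks hormone receptors. The targeted gene was UGT8, which encodes the ceramide galactosyltransferase of the endoplasmic reticulum. This enzyme makes galactosylceramide, from which sulfatide is formed. A clone with stable knockdown of UGT8 was hybridised to 1 array and the parental cells to 1 control array. With 1 array per group, no difference below has a replicate check, and none was tested. Differences are given as the log2 value of the knockdown array minus that of the control array, and each describes these 2 arrays. The knockdown cells were a clone and the control cells were the parental line, so clonal differences and the knockdown of UGT8 cannot be separated. The table held 49495 probe sets, and 10439 genes lay past the floor on mean level (log2 6.64). Both arrays had a median of 6.64, and their values correlated at r = 0.990 across probe sets, which are not independent replicates. The number of arrays limits the precision.

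The first comparison asked whether UGT8 was reduced in the cells labelled as knockdown. All 3 UGT8 probe sets were lower on the knockdown array. The brightest probe set read 8.95 on the control array and 6.61 on the knockdown array, a difference of -2.34 or 5.07-fold, leaving 19.7% of the control signal. Another went from 7.47 to 5.78 (-1.68, 31.2% of control). The remaining one went from 7.06 to 4.79 (-2.27), where the knockdown reading was at the mean of the background probe sets (4.73), so that this difference is a limit on its size. Over the 3 probe sets, this one included, the difference averaged -2.10 ± 0.36 (SD over probe sets of 1 pair of arrays, not over replicates). Of the genes past the floor, 2 had a lower difference than the brightest UGT8 probe set, ITGA10 and SLCO4C1.

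The next comparison asked which other transcripts differed between UGT8-knockdown and control cells. At least 2-fold, 77 genes were higher and 161 were lower, and 88.3% of genes lay within 1.5-fold. The linker histone gene H1-2 was 5.69-fold higher (2.51) and the core histone gene H2AC6 was 4.85-fold higher (2.28). CCNE2, which encodes cyclin E2, was 4.26-fold higher (2.09), and CDC25A, a phosphatase that activates cyclin-dependent kinases, was 3.49-fold higher (1.80). The replication fork protein gene TIPIN (1.62), the core histone gene H2BC12 (1.60), the replication checkpoint gene CLSPN (1.56) and the chromatin remodeller gene HELLS (1.55) followed. RIMS2, a gene of vesicle exocytosis, differed by 1.59, the mitochondrial protein gene GDAP1 by 1.56, TAGLN3 by 1.52 and the integrin activator gene FERMT1 by 1.51. In the other direction, ITGA10, a collagen-binding integrin subunit, was 7.11-fold lower (-2.83), and the organic anion transporter gene SLCO4C1 was 6.52-fold lower (-2.71). Complement factor B (CFB) was 4.65-fold lower (-2.22), the adhesion molecule gene VCAM1 4.53-fold lower (-2.18) and the integrin subunit gene ITGB8 4.32-fold lower (-2.11). CYTIP (-1.96), TMEM178A (-1.92) and SSPN (-1.89) came next. The hyaluronan synthase gene HAS2 and the hyaluronan-degrading factor gene CEMIP both differed by -1.85, as did PTGS2, the inducible prostaglandin synthase, which was 3.60-fold lower.

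Probe sets of these genes mostly pointed one way, though those of 1 gene are not all independent readings. Of the 34 genes at least 2-fold higher with at least 2 probe sets past the floor, 29 had all of them higher. Of the 98 such genes that were lower, 97 had all of them lower. H1-2 and H2AC6 were each read by 1 probe set marked for possible cross-hybridisation, and histone copies share sequence, so which copy was measured is uncertain. Averaged over all probe sets of a gene, dim ones included, H2BC12 differed by 0.95, FERMT1 by 0.79, ITGA10 by -1.52 and ITGB8 by -0.89. Without probe sets marked for cross-hybridisation, TMEM178A differed by -1.11. RNA-quality readings differed between the arrays for 1 of 2 genes: the 3' minus 5' difference of ACTB was 0.49 on the control array and 0.90 on the knockdown array, whereas that of GAPDH was 0.18 and 0.19. The control RNAs added at hybridisation were higher on the knockdown array, by a median of 0.51. Centring on them lowers every difference by that amount and turns the counts at 2-fold into 11 higher and 966 lower (1.13% higher, against 32.4% on the deposited scale). Centring on the poly-A control RNAs gave 54 higher and 196 lower (21.6% higher). Every direction given here and below is on the deposited scale, relative to the typical gene of these arrays, whose median difference was 0.03.

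**Figure D1:**
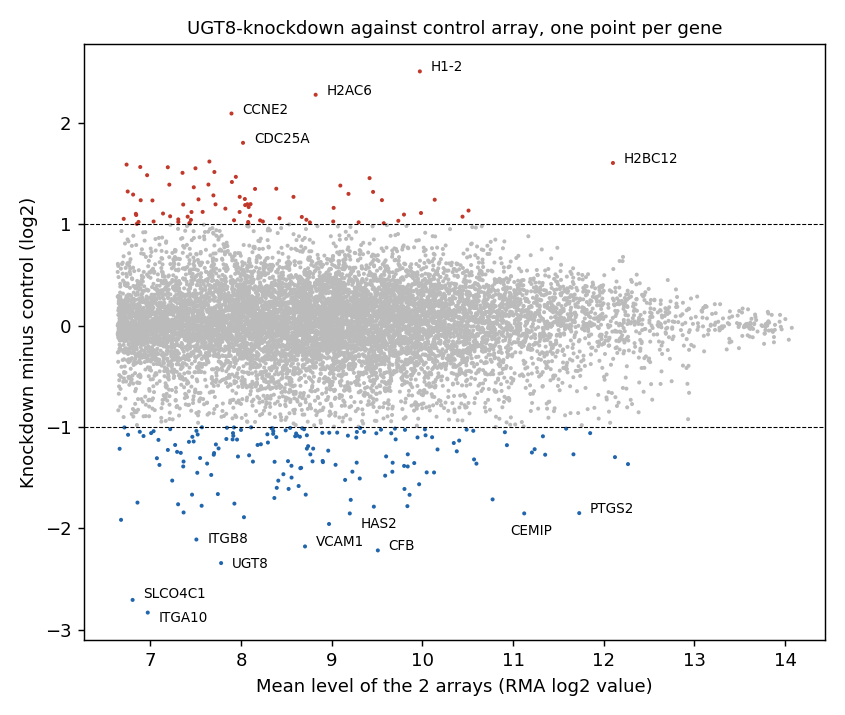
Each point is 1 of the 10439 genes past the floor, with its mean log2 level over both arrays on the x axis and its log2 difference, knockdown minus control on the deposited scale, on the y axis. Dashed lines mark 2-fold, red points are the 77 genes past it on the higher side and blue points the 161 on the lower side, with H1-2 (2.51) and ITGA10 (-2.83) at the ends.

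S and G1/S cell-cycle genes were higher on the knockdown array, and G2/M genes lay near 0. All 31 measured genes of the S and G1/S list were above 0, 24 of them by at least 1.5-fold, with a median difference of 0.85. After CCNE2 and CDC25A, the largest differences were those of the replication factor genes GINS2 (1.36) and MCM10 (1.35). The 31 measured G2/M genes had a median of 0.04, and none differed by 1.5-fold in either direction. Among 10000 random lists matched on mean level, the S and G1/S median lay above all of them, and the G2/M median lay at percentile 50.8. The list of D-type cyclins and CDK inhibitors, which also holds CDK4, CDK6, RB1 and MYC, had a median of 0.17 over 11 measured genes (percentile 87.4), and of 0.07 with no floor. Of these, CDK4 was higher by 0.67, and CDKN1C, an inhibitor of cyclin-dependent kinases, was lower (-0.76). On the scale centred on the hybridisation controls the S and G1/S median was 0.34.

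Integrin subunit genes were lower on the knockdown array. The 16 measured subunits had a median of -0.83, below all 10000 matched random lists, and 11 were at least 1.5-fold lower. After ITGA10 and ITGB8, ITGA1 was 3.39-fold lower (-1.76) and ITGB3 was 2.57-fold lower (-1.36). ITGAV (-0.79) and ITGB5 (-0.84), named in advance, were 1.72-fold and 1.79-fold lower. The 2 subunits above 0 were ITGAE (0.27) and ITGB1 (0.03). With no floor, which adds dim subunits, the integrin median was -0.14, still outside the central 95% of random lists. ITGB3 differed by -0.90 when all 7 of its probe sets were averaged, and by -1.45 over the 2 past the floor. The 21 measured components of focal adhesions and FAK signalling had a median of -0.15 (percentile 1.49). In this list FERMT1 was the only gene past 1.5-fold, and it was higher. That list was no longer outside the central 95% of random lists with no floor (-0.11) or without cross-hybridising probe sets (-0.13).

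Matrix genes and some mesenchymal markers were also lower. Of the 19 measured matrix proteases, inhibitors and crosslinkers, 7 were at least 1.5-fold lower and none higher (median -0.42, below all random lists). The metalloprotease gene ADAMTS1 differed by -1.10, the collagen crosslinker gene LOX by -0.87 and the protease inhibitor gene TIMP3 by -0.82. MMP3 (5.27 on the control and 7.24 on the knockdown array, 1.96) and TIMP4 (6.18 and 6.85, 0.67) were higher but below the floor on mean level. With no floor this median was -0.19, still outside the central 95%. The 19 measured mesenchymal markers had a median of -0.20 (percentile 0.27), with 14 below 0 and 7 at least 1.5-fold lower. The 5 above 0 were TAGLN (0.35), CDH2 (0.21), SPARC (0.08), ACTA2 (0.05) and VIM (0.01). The collagen gene COL3A1 (-1.53), the proteoglycan gene LUM (-1.34) and the cadherin gene CDH11 (-1.27) led the mesenchymal list. Its median was -0.11 without cross-hybridising probe sets, inside the central 95%, and -0.11 with no floor and -0.35 after averaging, both outside. COL3A1 and LUM also belong to the list of fibroblast markers, of which 6 of 15 lay past the floor and 4 of these 6 are held by another list. The fibroblast list had a median of -0.88, below all random lists, and included COL6A3 (-1.32). With the floor at the 25th percentile its median was -0.45, and with no floor it was -0.11, no longer outside. Of other cell types, 5 endothelial markers had a median of -0.10 (percentile 23.1) with PECAM1 lower (-1.09). Only 4 leukocyte markers lay past the floor, too few for a percentile, with CD8A at 1.02 and CD14 at -0.73. CD8A differed by 0.63 when both of its probe sets were averaged.

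The 18 measured epithelial junction and identity genes had a median of -0.20 (percentile 0.41), with the transcription factor gene ELF3 (-0.96) and the polarity gene LLGL2 (-0.95) lower and the adhesion molecule gene EPCAM higher (0.62). This list was inside the central 95% under each other floor, after averaging of probe sets, and without cross-hybridising probe sets, with medians between -0.15 and -0.05. LLGL2 differed by -0.60 when its probe sets were averaged. The 12 luminal markers had a median of -0.12 (percentile 9.98), with MLPH (-0.61) and SPDEF (-0.61) lower. After averaging of probe sets the luminal median was -0.29, outside the central 95%, and with no floor it was 0.06. The 8 basal markers had a median of -0.12 (percentile 10.6), and none reached 1.5-fold. Without cross-hybridising probe sets the basal median was -0.03.

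The NF-kappaB, TGF-beta and metastasis lists had medians below all of their random lists. Of the 22 measured NF-kappaB targets, 7 were at least 1.5-fold lower and none higher (median -0.47). Besides VCAM1 and PTGS2, these included the chemokine gene CXCL2 (-0.91) and the cytokine gene IL6 (-0.81). CCL20, below the floor on mean level, was lower (-1.31). Of 26 measured TGF-beta pathway and target genes, 7 were at least 1.5-fold lower and 1 higher (median -0.32). TGFB2, a TGF-beta ligand, differed by -1.09 and LTBP1, which binds latent TGF-beta, by -0.97. ID3, an inhibitor of helix-loop-helix transcription factors, was 2.11-fold higher (1.07). Of 22 measured breast cancer metastasis genes, 9 were at least 1.5-fold lower and none higher (median -0.35). That list also holds VCAM1 and PTGS2, followed by the osteopontin gene SPP1 (-1.44) and the adhesion scaffold gene NEDD9 (-1.27). NEDD9 differed by -0.83 when all 4 of its probe sets were averaged, and by -1.15 over the 3 past the floor. ST6GALNAC5, of this list but below the floor on mean level, was higher (5.34 on the control and 6.88 on the knockdown array, 1.54). The metastasis median was -0.23 with no floor and -0.61 with the floor at the 75th percentile, both outside the central 95%. The 14 Notch genes had a median of -0.39 (percentile 0.03), with the coactivator gene MAML2 (-1.21), the ligand gene DLL1 (-0.85) and LFNG (-0.78) lower. With no floor or the floor at the 25th percentile the Notch median was -0.17, and DLL1 differed by -0.20 after averaging. The 18 Wnt genes had a median of -0.27 (percentile 0.06), with LGR5 (-1.75) and the coreceptor gene LRP5 (-1.08) among the 6 at least 1.5-fold lower, and a median of -0.47 with the floor at the 75th percentile. The 22 YAP and TEAD targets had a median of -0.22 (percentile 0.20), and 5 were at least 1.5-fold lower, TGFB2, RBMS3 (8.61 on the control and 7.61 on the knockdown array), IGFBP3 (-0.91), CRIM1 (-0.68) and CCN1 (-0.66).

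Lipid synthesis and hypoxia genes were lower as groups. Of 19 measured genes of cholesterol synthesis and uptake, 18 were below 0 and 7 at least 1.5-fold lower (median -0.57, below all random lists). The sterol sensor gene INSIG1 (-1.06), the synthase gene HMGCS1 (-0.94) and the squalene epoxidase gene SQLE (-0.92) led them. Of 18 genes of fatty acid synthesis and desaturation, 16 were below 0 and 7 at least 1.5-fold lower (median -0.38, below all random lists). ACSS2, an acetyl-CoA synthetase, was 3.18-fold lower (-1.67), and the desaturase genes FADS1 and SCD differed by -0.99 and -0.92. With no floor the fatty acid median was -0.20, still outside the central 95%. Of 19 hypoxia targets, 17 were below 0 and 6 at least 1.5-fold lower (median -0.48, below all random lists). The prolyl hydroxylase gene EGLN3 (-1.39), the mTOR inhibitor gene DDIT4 (-1.27) and NDRG1 (-0.95) led this list, which also holds LOX. EGLN3 differed by -0.88 when its probe sets were averaged, and NDRG1 by -1.50 without cross-hybridising ones. The 29 lysosomal genes had a median of -0.27 (percentile 0.01), and 5 were at least 1.5-fold lower. These were the cholesterol exporter gene NPC1 (-1.18), TPP1 (-0.78), NAGLU (-0.73), MAN2B1 (-0.65) and CTSD (-0.61). TPP1 differed by -0.33 after averaging and by -0.13 without cross-hybridising probe sets. Glycolysis genes had a median of -0.08 over 21 members (percentile 5.37), with ALDOC lower (-0.84), or -0.43 without cross-hybridising probe sets. The glycolysis list was outside the central 95% after averaging (-0.17) and without those probe sets (-0.23). The 34 genes of oxidative phosphorylation had a median of 0.10 (percentile 90.4), and ATP5MC1 was the one past 1.5-fold (0.77).

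Other genes of sphingolipid metabolism differed less than UGT8. The 8 measured genes of galactosylceramide and sulfatide metabolism, UGT8 among them, had a median of -0.12 (percentile 9.61). That median was -0.05 with the floor at the 75th percentile and -0.21 without cross-hybridising probe sets. GALC, the lysosomal galactosylceramidase, was 1.63-fold lower (-0.70) and was, with UGT8, the only member past the floor that differed by at least 1.5-fold. The sulfotransferase gene GAL3ST1 (-0.62) and the arylsulfatase gene ARSA (0.01) lay below the floor on mean level. The 12 genes of glucosylceramide and ganglioside metabolism had a median of -0.05 (percentile 24.2), with the glucosylceramide synthase gene UGCG 1.85-fold lower (-0.88). That median was -0.19 with the floor at the 75th percentile and -0.18 after averaging. The 22 genes of ceramide and sphingomyelin metabolism had a median of -0.12 (percentile 5.77), with the sphingomyelin synthase gene SGMS2 lower (-0.84, or -0.52 after averaging). After averaging, the median of this list was 0.01. None of the 14 genes in the list of the UDP-glycosyltransferase family lay past the floor.

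Immune and stress lists were mixed. The 26 measured interferon response genes had a median of 0.22 (percentile 99.7), with IFIT2 (1.02), IFIT1 (0.87), OAS2 (0.68) and ISG15 (0.60) at least 1.5-fold higher and IFITM1 lower (-1.37). With the floor at the 75th percentile, which keeps the brighter members, the interferon median was -0.31. After averaging of probe sets, and without cross-hybridising ones, it was 0.18, inside the central 95%. OAS2 differed by 0.31 after averaging. The 21 antigen presentation genes had a median of -0.37, below all random lists, with HLA-DRA (-0.90), HLA-E (-0.82), HLA-F (-0.65) and CD74 (-0.59) at least 1.5-fold lower. HLA genes share sequence, and without cross-hybridising probe sets the list median was -0.15, inside the central 95%. That median covers fewer genes, as HLA-E had no probe set left. HLA-DRA was then read by a probe set below the floor, which differed by 0.11, whereas both of its probe sets past the floor were lower. HLA-F differed by -0.29 after averaging of all 10 probe sets, and by -0.56 over the 4 past the floor. The 27 apoptosis regulators had a median of 0.19 (percentile 98.1) and a mean of 0.01, with BAK1 (0.70), CASP2 (0.65) and BIK (0.64) higher and the death ligand gene TNFSF10 (-1.79), BBC3 (-1.07) and BMF (-0.69) lower. This list was inside the central 95% with each other floor, after averaging of probe sets (0.18) and without cross-hybridising ones (0.02). BAK1 differed by 0.40 and BMF by -0.28 after averaging, and BAK1 by 0.28 without cross-hybridising probe sets. The 26 unfolded protein response and ATF4 genes had a median of -0.13 (percentile 1.03), with EDEM1 (-0.75), VLDLR (-0.70) and DNAJB9 (-0.64) lower. That median was -0.24 with the floor at the 75th percentile and -0.26 without cross-hybridising probe sets. The 13 heat-shock genes had a median of 0.19 (percentile 96.2), and none reached 1.5-fold. That median was 0.21, outside the central 95%, with no floor or the floor at the 25th percentile. Without cross-hybridising probe sets the heat-shock median was 0.28. On the scale centred on the hybridisation controls the interferon and apoptosis medians were -0.29 and -0.33.

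Growth factor and transcription factor lists showed members in both directions. The 19 receptor tyrosine kinase and ligand genes had a median of -0.22 (percentile 0.45). The ligand gene NRG1 was 2.46-fold higher (1.30), whereas the ligand genes EREG (-1.10), TGFA (-1.08) and PDGFA (-0.72) and the receptor genes DDR1 (-0.73) and IGF1R (-0.63) were lower. After averaging NRG1 differed by 0.49 and TGFA by -0.58, and with the floor at the 25th percentile the list median was -0.07, inside the central 95%, and with no floor it was -0.09. The 26 immediate early and AP-1 genes had a median of -0.12 (percentile 1.97), with EGR1 (-1.10), DUSP6 (-0.91), SPRY4 (-0.74) and SPRY2 (-0.64) lower and FOSL1 higher (0.71). With no floor or the floor at the 25th percentile that median was -0.11, and without cross-hybridising probe sets it was -0.14, both inside the central 95%. After averaging it was -0.20, outside, and with the floor at the 75th percentile it was -0.19. EGR1 differed by -0.62 after averaging. The 21 p53 targets had a median of -0.08 (percentile 9.94), with TP53I3 (1.11) and AEN (0.84) higher and BBC3, TP53INP1 (-0.94) and XPC (-0.70) lower. TP53INP1 differed by -0.50 after averaging. The 21 NRF2 targets had a median of -0.09 (percentile 6.13), with the haem oxygenase gene HMOX1 higher (0.79) and ABCC3 lower (-0.75). After averaging of probe sets the NRF2 median was -0.02. ABCC3 differed by 0.26 without cross-hybridising probe sets, where it was read by a probe set below the floor. Of members below the floor on mean level with a reading above it on 1 array, the NRF2 target AKR1C1 differed by -1.56 and the receptor genes PDGFRB and FGFR3 by -0.75 and 0.61.

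The ribosomal and housekeeping lists, which served as reference, lay near 0 on the deposited scale, where normalization removes a shift common to most transcripts. The 37 cytosolic ribosomal protein genes had a median of -0.00 (percentile 14.4), and none reached 1.5-fold. The 15 housekeeping genes had a median of -0.01 (percentile 26.5), with POLR2A, a subunit of RNA polymerase II, higher (0.68, or 0.25 after averaging). Of the 2 POLR2A probe sets past the floor, only 1 was higher. In both lists the mean was above 0, at 0.02 and 0.04. The 14 genes of RNA interference had a median of 0.11 (percentile 77.1), and none reached 1.5-fold. Of the cancer-testis antigens, 1 gene lay past the floor, MAGEB2 (0.83). Of the 39 lists with at least 5 measured genes, 23 had a median outside the central 95% of their random lists. These were 3 above and 20 below, where 1.95 would be outside if list members were unrelated random genes. The lists share genes and their members are coexpressed, so more than 1.95 could lie outside without any effect of the knockdown. These are not independent counts and describe these 2 arrays.

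**Figure D2:**
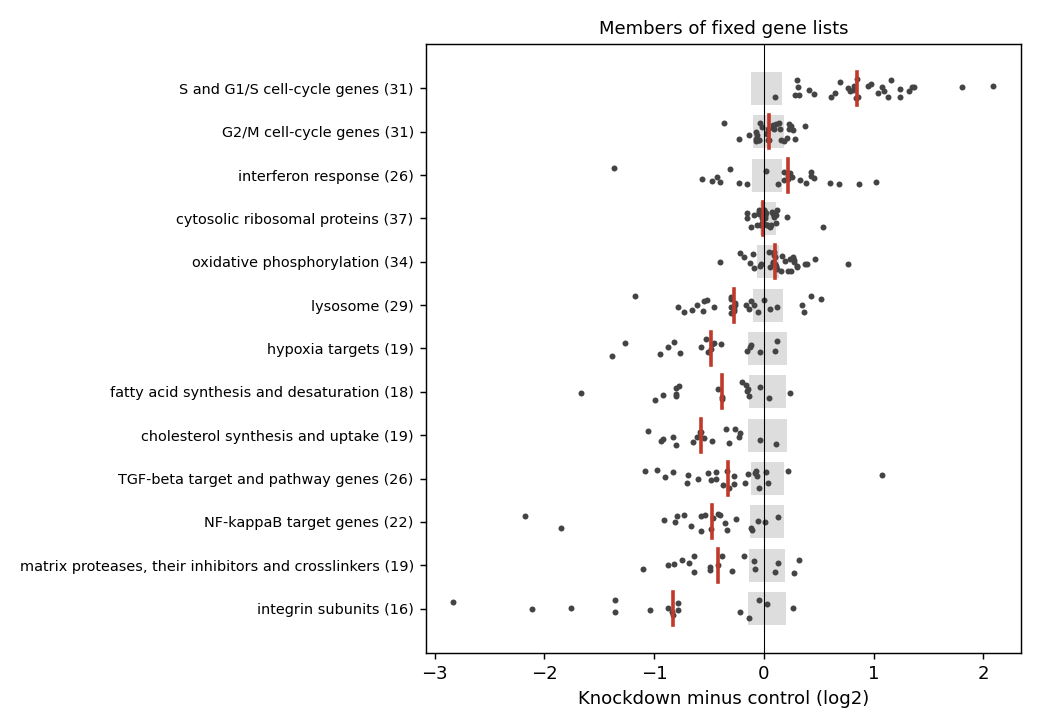
Log2 difference, knockdown minus control on the deposited scale, on the x axis for the genes of 13 of the 42 lists, with 1 point per gene past the floor, random vertical jitter and the number of genes in parentheses. Red lines are list medians and grey bars the central 95% of medians of matched random lists, which the S and G1/S median (0.85) exceeds and the integrin median (-0.83) falls below.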

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

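The tests on the spike-in controls and the test of mean level were chosen after the results were seen. So were the tests of cycling cells and of fibroblast transcripts, whereas those of gene span and of neighbouring genes were chosen before their results were seen.

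Control probe sets outside the comparison gave a signal that differed between the arrays. The 18 probe sets of the bacterial and phage RNAs added at hybridisation (bioB, bioC, bioD and cre) were all higher on the knockdown array, by a median of 0.51 and a range of 0.22 to 0.66. A lower amount of mRNA per total RNA in the knockdown cells would raise the poly-A controls by as much, if these were added to total RNA as is usual. All 24 poly-A probe sets had a median difference of 0.08 (-0.16 to 0.40, 18 higher). The 6 of dap, read between 6.59 and 8.49 on the control array while the 24 averaged 5.79, had one of 0.0074. This lay below the lowest hybridisation control at 0.215, so the dap probe sets did not rise by as much. They are 6 of the 24 and were picked after the values were seen, so a lower amount of mRNA is not excluded. Less labelled cRNA on the knockdown array relative to the added RNAs may also raise all hybridisation controls (0.215 at the lowest), but this was proposed from these values, so they do not test it, and it stays open because the amounts added are not given in the sources used here.

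The 28S rRNA control probe sets were also higher on the knockdown array, by a median of 0.78 over 3 probe sets (0.09 to 0.97), against 0.15 for the 3 probe sets of 18S rRNA.

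The pattern of higher S and G1/S genes with G2/M genes near 0 was weighed against 3 explanations. A trend of the difference with mean level would shift random lists of the same mean levels alike, but 95% of these lay between -0.11 and 0.17, against an S and G1/S median of 0.85. This repeats the comparison with matched random lists given above. A trend with gene span would be removed with that trend, but the median was 0.80 afterwards, with random lists between -0.14 and 0.14. A larger share of cells in every phase alike would raise both lists, but their medians lay 0.81 apart, where reassigning genes between the lists gave gaps within 0.40 of 0 in 95% of draws. Both medians define the pattern, so this gap restates it, and reassigned genes are not coexpressed as list members are. A difference in the share of cells in S phase, through UGT8, through the clone or through culture density at harvest, may underlie the pattern, and 1 array per group leaves these untested.

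The lower integrin and collagen genes were weighed against 3 technical explanations. Fibroblasts in the control culture would bring COL1A1, COL1A2 and DCN, but these read 6.04, 5.47 and 4.60 on the control array, all below the floor, with a median difference of 0.0943, although DCN alone was lower (-0.49). These 3 were picked after the values were seen. The fixed list of fibroblast markers was lower (median -0.88, all 6 measured markers below 0), though 4 of these 6 are held by another list. The 3 readings alone therefore do not exclude fibroblasts. After removal of the trend with gene span the integrin median was -0.87, with random lists between -0.17 and 0.17, and that of 16 collagen genes was -0.54, with random lists between -0.19 and 0.17. Loss of gene copies around most of the 21 integrin and collagen genes at least 1.5-fold lower would lower the median of their neighbours. The 107 neighbours had a median of -0.0080 (quartiles -0.27 and 0.24). As it pools all loci, this median cannot exclude a loss at a few of them. UGT8, the selection of a clone or culture conditions may each underlie these differences, and none of these was tested, since 1 array per group cannot separate them.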

How the results depend on the processing

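Centring on the spike-in controls was chosen after the results were seen. All other alternatives were planned. The 2-fold counts of 77 higher and 161 lower became 518 and 704 at 1.5-fold and 7 and 29 at 3-fold, by construction of the threshold. They were 118 higher with no floor, 117 higher with the floor at the 25th percentile, 21 and 84 with it at the 75th, 46 and 99 with the mean over probe sets, and 143 and 378 with each probe set singly. UGT8 differed by -2.10 with the mean over probe sets. With centring on the hybridisation controls it differed by -2.85, and the counts were 11 and 966, as a shift of every value by 0.51 gives. The lower genes outnumbered the higher ones under every alternative run. The number of lists outside their random lists was between 16 and 23. Of the lists outside their random lists, those with reversed medians were the interferon list (-0.31 with the floor at the 75th percentile, where the dimmer members drop out, and -0.29 with hybridisation centring) and the apoptosis list (-0.33 with hybridisation centring). Hybridisation centring also turned the positive medians of the G2/M, cyclin, oxidative phosphorylation, heat-shock and RNA interference lists negative. Other sign changes of lists inside the bounds were luminal (0.06 with no floor), G2/M (-0.03 with poly-A centring), and ceramide (0.01) and ribosomal (0.02) with the mean over probe sets. HLA-DRA (0.11) and ABCC3 (0.26) reversed without cross-hybridising probe sets, where each was read by a probe set below the floor. Loess centring moved no list across the bounds and no named gene by over 0.1, and median, poly-A and hybridisation centring, which subtract a constant, cannot move a percentile. The mean over probe sets, which includes those below the floor, moved 61 of 119 named genes by over 0.1. It turned the sign of none but ARSA, near 0 at 0.01 and then -0.01. No paired analysis was possible because each group holds 1 array, and no replicate could be left out. Lists left with fewer than 5 measured genes under an alternative gave no value there. The floor of 6.64 lies above the mean of background probe sets (4.73 on both arrays), and the difference of a gene near that background understates its change.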

Other observations

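The gene families described here were chosen after the data were seen, as was the test of adjacent genes. Several gene families were higher on the knockdown array as groups. Of 73 mitochondrial ribosomal protein genes, 68 were above 0, with a median of 0.38, and 12 were at least 1.5-fold higher, among them MRPL21 (0.85). Of 29 RNA polymerase subunit genes, 28 were above 0 (median 0.35), with POLR3G at 1.19. Of 34 proteasome subunit genes, 28 were above 0 (median 0.33), and none reached 1.5-fold. Of 21 nucleoporin genes, 20 were above 0 (median 0.31), and 1, NUP155 (0.63), was at least 1.5-fold higher. The 9 measured histone genes had a median of 0.85, with H2BC5 at 0.92. Of these, 8 were above 0 and H1-10 was lower (-0.42). They include H1-2, H2AC6 and H2BC12, already named for the size of their differences, so this median partly restates those genes. On the scale centred on the hybridisation controls, which lowers all of these by 0.51, the histone median alone stays above 0. The 201 solute carrier genes and the 238 zinc finger genes both had a median of 0.01.

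Collagen, complement, cytokine receptor and chemokine genes were lower as groups. Of 16 measured collagen genes, 15 were below 0 and 10 at least 1.5-fold lower (median -0.65), with COL12A1 at -1.38. Complement genes had a median of -0.36 over 9 genes. CFB (-2.22), C1R (-1.51), C1RL (-1.47) and C1S (-1.12) were at least 1.5-fold lower, and C3 was higher (0.61). Of 22 cytokine receptor genes, 7 were at least 1.5-fold lower (median -0.39), including LIFR (-1.52), LEPR (-1.47), IL1RAP (-1.33) and OSMR (-1.24). The 7 measured chemokine genes had a median of -0.40. The arrestin-domain genes TXNIP (-0.85) and ARRDC4 (-1.61), both known to respond to glucose, were lower as well.

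The difference was related to gene span and position. Across 10430 genes, which are not independent replicates, it correlated with the log10 span at r = -0.17. The 2608 shortest genes had a median of 0.07 and the 2608 longest one of -0.09. Neighbouring genes along a chromosome had correlated differences (r = 0.0950), where 1000 shuffled orders gave at most 0.0339.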
